A study of Homo sapiens with 64 samples.

How the data were processed

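Total RNA from human lymphoma cell lines was measured on 64 Illumina single-channel expression arrays spread over 7 slides. Per the labels, RNA was extracted with the Qiagen RNeasy kit, had an integrity number above 8, and was turned into biotin-labelled cRNA with the Ambion TotalPrep kit. The array model, its genome build, the dose of OTX015 and the scanner settings are not given in the sources used here, so no coordinates are printed.

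The deposited signal table holds one linear intensity per probe and array, neither scaled between arrays nor background-subtracted, and has no detection p-values or control probes. The deposited processed table holds log2 values. How the authors made it is not given in the sources used here. Set beside log2 of the signals, it lacked background subtraction, and its scale and centring were read from this comparison: the 42 arrays of the treated lines had medians of 6.64 and the 22 panel arrays medians of 6.74, each set being alike in distribution within itself. Quantile normalization of log2 signals within each set came within a median absolute difference of 0.0107 and 0.0246 of the deposited values, the latter without Karpas-422. The arrays have a single channel, so no direction of a ratio applies. For 63 of 64 arrays the processed column matched the array's own signals best, the exception being the array labelled Karpas-422.

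Of 47231 probes, 30113 carried one gene symbol, 8 carried several and 17110 carried none. No symbol needed updating against the reference annotation. Probes without a symbol were used only in the closing section.

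The plan assumed deposited detection p-values. In their place, the lower side of each array's background mode was mirrored to give a background distribution, and a probe was kept when its p under that distribution was below 0.01 on at least 3 of the 42 arrays of the treated lines. This kept 26047 probes, 60.49% of those with a symbol and 45.75% of those without. Signals were corrected with limma's normexp (offset 16), quantile normalized over all 64 arrays and put on the log2 scale. Each gene was represented by its detected probe with the highest mean, which gave 13403 genes, 3679 of them with more than one detected probe. A gene is called uncertain where another of its detected probes changed the opposite way.

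The median signal per array was 88.55 to 115.5 in the treated lines and 88.27 to 118 in the panel, with 33.85 to 42.06% and 36.92 to 47.15% of probes detected. For arrays, the number of arrays limits the precision. The labels do not say whether the 3 replicates of a group came from separate cultures, so the p-values measure only the spread between these arrays.

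The 42 arrays formed 14 groups of 3: each of SUDHL2 and SUDHL6 not treated, and with DMSO or OTX015 for 1, 2 or 12 h. One linear model with a mean per group was fitted with limma (lmFit, then eBayes with an intensity trend), and 18 contrasts were tested with Benjamini-Hochberg adjustment over the genes of each contrast at 0.05. The tests were 2-sided. Standard errors (SE) come from limma's moderated spread, pooled over the 14 groups. The contrasts were OTX015 against DMSO at each hour in each line, DMSO against not treated likewise, the difference between lines in the OTX015 response at each hour, the 12 h minus 1 h OTX015 response in each line, and SUDHL2 against SUDHL6 not treated. Where the probe of a gene was detected on no array of one group, the fold is given as a lower bound: the mean of the other group minus the mean, over the undetected arrays, of the larger of the gene's value and the lowest value of a detected probe.

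There were 23 gene lists: MYC and ribosome biogenesis targets; NF-kB targets; the Toll-like receptor and MYD88 pathway; JAK-STAT and cytokine signalling; interferon response; histone genes; BET proteins and P-TEFb control; the BCL2 family; B-cell receptor signalling; germinal centre B-cell genes; activated B-cell and plasma cell genes; immediate early genes; E2F and DNA replication genes; mitosis genes; p53 targets and cell cycle inhibitors; cholesterol synthesis; amino acid stress and unfolded protein response; heat shock; antigen presentation; reference genes; and markers of T and NK cells, myeloid cells, and stromal and epithelial cells. Lists were tested against all other genes with camera (preset correlation 0.01, adjusted over 138 tests for each of the OTX015 and DMSO families, 69 for the differences between lines and 23 for the untreated lines), again with the correlation estimated from the data, and with fry. These lists, the contrasts and their tests, the rule for naming genes and all alternatives except 4 were fixed before the data were examined. The 4 added later were a filter at 1.5 times the background mode, a normexp offset of 50, the panel without Karpas-422, and the third SUDHL6 experiment left out. The slide test of the DMSO arrays, the S phase test of the histone genes and the count of detected groups behind each difference between responses were also chosen later. Such a difference is given as a lower bound where only groups that would enlarge it were undetected, and without a size where other groups were undetected.

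Genes were named by a rule. Among genes with an adjusted p under 0.05 and all 3 arrays of one group above all 3 of the other, the 8 largest rises and 8 largest falls were taken at 12 h and in the untreated lines, 5 and 5 at 1 h and 2 h, and 2 and 2 for DMSO. For differences between lines or hours it was 4 and 4 by adjusted p alone. To these came up to 4 members per list with the lowest adjusted p, and a fixed set given whatever its result: MYC, HEXIM1, BRD2, BRD3, BCL2, BCL6, IRF4, MYD88, IL6, IL10, PIM1, CCND2, CDKN1A, NFKBIA, MYB, TCF3, E2F1, CCR7 and SERPINI1. Another planned gene, and a planned panel relation that needs it, are not reported here. Unnamed loci and sex-linked marker genes were passed over.

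Whether equal replicate numbers pair the arrays was checked by correlating residuals across genes within each contrast. All 3 same-number pairs exceeded 0.1 only for OTX015 against DMSO in SUDHL6 (0.204, 0.123 and 0.386 at 1 h; 0.183, 0.177 and 0.431 at 2 h; 0.281, 0.222 and 0.441 at 12 h). With the experiment number as a block, the counts of genes changed there were 158, 1024 and 3974, in place of 110, 804 and 3597. Slide was tested as a block. Alternatives also covered no background correction, scaling to the 75th percentile, normalizing the 42 arrays alone, the authors' values, detection filters, every probe or the mean of a gene's probes, array weights, only the groups compared, untreated arrays in place of DMSO, and each array left out in turn.

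Across the 22 panel lines, 2 relations were computed with permutation tests of 100000 resamples and their 4 p-values adjusted together. Recovery was tested on simulated data, in which 200 genes were changed by 1.5, 2 or 4-fold within the spread of the real groups. For the 6 OTX015 contrasts, 49.3 to 61.2% of the 1.5-fold changes, 95.5 to 98.5% of the 2-fold changes and 100% of the 4-fold changes were called, with 5 to 14 false calls. Tools were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.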

Results

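The data are gene expression profiles of lymphoma lines grown in vitro. SUDHL2 and SUDHL6 were each profiled not treated, after DMSO, the solvent used as vehicle, and after OTX015, a small molecule that keeps the BET bromodomain proteins from binding acetylated histones. Treated arrays were taken at 1, 2 and 12 h, with 3 arrays in each of the 14 groups. A panel of 22 untreated lymphoma lines, 1 array each, gives basal levels. Replicate arrays correlated at 0.983 to 0.995. After each gene below, the bracket gives the log2 fold change ± SE (3 against 3 arrays) with limma's adjusted p. For the genes named first in each comparison, all 3 arrays of one group lay above all 3 of the other.

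Which genes respond first to BET inhibition was asked at 1 h in SUDHL2. The largest falls were of the surface activation marker CD69 (-2.21 ± 0.44, adjusted p = 0.0082) and the nuclear receptor NR4A2 (-1.55 ± 0.18, adjusted p = 4.5e-07). A microRNA host gene, MIR3142HG (-1.33 ± 0.15, adjusted p = 4.5e-07), and the cytokine TNF (-1.24 ± 0.16, adjusted p = 4.7e-06) followed, with NFYC-AS1 next (-1.08 ± 0.15, adjusted p = 1.8e-05). The mean log2 intensities of CD69 (7.13), NR4A2 (6.33) and TNF (8.54) with OTX015 were above the untreated 6.57, 5.7 and 7.71, so these fell against DMSO only. Among the rises were RPPH1 (1.26 ± 0.23, adjusted p = 0.003), LSMEM1 (1.20 ± 0.18, adjusted p = 1e-04), RNU5A-1 (1.14 ± 0.22, adjusted p = 0.006) and SNORD31 (0.82 ± 0.18, adjusted p = 0.021). HOXB2, detected on no DMSO array, was at least 1.62-fold higher (adjusted p = 0.0045). In all, 7 genes rose and 18 fell of 13403, 9 of them at least 2-fold. By comparison, 10.1% of genes had arrays that did not overlap between the groups, where chance gives 10%. MYC (-0.55 ± 0.22, adjusted p = 0.97) moved most of the fixed set of genes. None of that set passed, HEXIM1 (adjusted p = 1) being below background with DMSO, where 572 of all genes had an unadjusted p under 0.05.

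Among the lists in SUDHL2 at 1 h, NF-kB targets shifted down (median -0.20, camera adjusted p = 2.2e-06; adjusted p = 0.10 with an estimated correlation). TNF and 1 other of 22 had fallen, 2 adjusted over the list alone. Histone genes shifted up (median 0.21, adjusted p = 2.5e-05; adjusted p = 0.44 with an estimated correlation). H2BC21 (1.02, adjusted p = 0.069) did not pass over all genes and was the 1 of 23 that passed adjusted over the list alone. Immediate early genes shifted down (median -0.03, mean -0.18, adjusted p = 0.00042; adjusted p = 0.25 with an estimated correlation). Over all genes 2 of 20 had fallen, and 5 adjusted over the list alone. The amino acid stress list also shifted down (median -0.13, adjusted p = 0.0012; adjusted p = 0.11 with an estimated correlation), a call lost with 75th percentile scaling. MYC targets did not shift (median -0.05, adjusted p = 0.24). The calls of HOXB2 and SNORD31 were lost without OTX015 replicate 1 or DMSO replicate 1, and that of SNORD31 also without DMSO replicate 2 and with the authors' values. RNU5A-1 lost its call without DMSO replicate 3, and CD69 without OTX015 replicate 1 or DMSO replicate 3. The count of 25 was 15 without OTX015 replicate 1 and 16 without DMSO replicate 1 or 2.

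At 2 h in SUDHL2, the oncogene MYC fell by 1.74 ± 0.22 on the log2 scale (adjusted p = 7.8e-07). With it fell the orphan receptor GPR18 (-2.23 ± 0.33, adjusted p = 1.1e-05), the host gene of miR-155, MIR155HG (-1.66 ± 0.18, adjusted p = 2.4e-08), and FCGBP (-1.66 ± 0.18, adjusted p = 2.4e-08). ARHGEF10, detected on no OTX015 array, was at least 2.27-fold lower (adjusted p = 8.2e-09). The germinal centre repressor BCL6 (-1.42 ± 0.18, adjusted p = 8e-07), the kinase gene PIM1 (-0.94, adjusted p = 0.00043) and IL6 (-0.73, adjusted p = 0.00051) also fell. LSMEM1 (2.19 ± 0.18, adjusted p = 5.2e-11) and the histone gene H2BC21 (1.92 ± 0.25, adjusted p = 9.2e-07) rose most. They were followed by IQCN (1.88 ± 0.43, adjusted p = 0.0053), ADARB1 (1.80 ± 0.18, adjusted p = 6.8e-09, detected on 2 of 3 DMSO arrays) and TEX14 (1.80 ± 0.19, adjusted p = 1.3e-08, detected on 1 of 3). The cell cycle inhibitor CDKN1A rose (0.77, adjusted p = 0.0065). In total 111 genes rose and 329 fell, 49 of the 440 at least 2-fold, and 15.8% of genes did not overlap.

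Histone genes as a list were up in SUDHL2 at 2 h (median 0.46, adjusted p = 2e-08; adjusted p = 0.25 with an estimated correlation). Of 23 members 4 rose, 8 adjusted over the list alone, among them H2AC20 (0.93). Of 20 immediate early genes 4 rose and 1 fell, 6 and 2 adjusted over the list alone. The list had a median of 0.31 (adjusted p = 2.4e-05; adjusted p = 0.16 with an estimated correlation). IER3 (1.5, adjusted p = 2.9e-06) and JUNB (1.04, adjusted p = 0.00022) were up. NF-kB targets stayed down (median -0.20, adjusted p = 0.00042; adjusted p = 0.21 with an estimated correlation). Here 4 of 22 had fallen, CD83 (-1.01, adjusted p = 2.7e-05) among them. Mitosis genes were shifted down (median -0.21, adjusted p = 0.0015; adjusted p = 0.63 with an estimated correlation), with 1 of 20 fallen and 5 adjusted over the list alone. Heat shock genes were shifted up (median 0.15, adjusted p = 0.0066; adjusted p = 0.10 with an estimated correlation), DNAJB1 (0.66, adjusted p = 0.0071) being the 1 of 10 that rose. The MYC list did not move (median -0.01, adjusted p = 0.94). GPR18 (6.62 with OTX015, 6.42 untreated) and CD83 (9.81 and 9.63) fell against DMSO only. The other 13 measured genes of the fixed set lay between CCR7 (-0.33) and IRF4 (0.36) with adjusted p of 0.5 or more, and CCND2 was below background in both groups. IQCN lost its call without OTX015 replicate 2, DNAJB1 without OTX015 replicate 1 and CDKN1A with the mean of its probes. The count of 440 was 289 without OTX015 replicate 1.

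After 12 h, histone genes made up most of the largest rises in SUDHL2. H2BC21 rose 22.9-fold (4.51 ± 0.25, adjusted p = 5.3e-18), followed by H2AC20 (4.25 ± 0.20, adjusted p = 6.9e-20), H2AC19 (4.21 ± 0.24) and H2AC18 (3.95 ± 0.32). Next came H2BC11 (3.81 ± 0.32), H2AJ (3.76 ± 0.21), H1-2 (3 ± 0.12, adjusted p = 9.2e-22) and H4C14 (2.96 ± 0.18). MYC fell 11.1-fold (-3.48 ± 0.22, adjusted p = 4.6e-16), beside the scavenger receptor CD36 (-3.46 ± 0.16, adjusted p = 3.1e-20), and the interleukin subunit IL12A (-3.42 ± 0.17, adjusted p = 3.5e-19). Further falls were of the A20-binding protein TNIP3 (-3.14 ± 0.16), MARCHF1 (-3.03 ± 0.19) and SMPDL3A (-2.87 ± 0.15). PTGDR and the interleukin 2 receptor gene IL2RA were at least 4.45-fold (adjusted p = 2.1e-16) and 6.24-fold lower (adjusted p = 4.9e-13), with no OTX015 array above background. In all 2364 genes rose and 2205 fell, 34.1% of those tested, 754 of them at least 2-fold. Of all genes, 44.7% did not overlap.

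Of the fixed set, several more genes fell in SUDHL2 at 12 h: IL6 (-2.09 ± 0.14, adjusted p = 1.2e-15), the plasma cell factor IRF4 (-1.79 ± 0.20, adjusted p = 1.2e-09), BCL6 (-1.56 ± 0.18, adjusted p = 3.9e-09) and MYB (-1.08, adjusted p = 5.6e-07). So were PIM1 (-0.96, adjusted p = 2.2e-05), the Toll-like receptor adaptor MYD88 (-0.66, adjusted p = 1.5e-05) and BCL2 (-0.55, adjusted p = 0.013, passed by 2 of its 4 probes). With OTX015 mean PIM1 was 9.06, near the untreated 9.08, with 10.02 for DMSO. MYD88 was at 7.87, above the untreated 7.47 and below the 8.53 of DMSO, so both are lower against DMSO only. The chemokine receptor CCR7 (1.83 ± 0.45, adjusted p = 0.0012), SERPINI1 (1.66 ± 0.22, adjusted p = 4.8e-08), CDKN1A (1.40, adjusted p = 3.5e-08), BRD2 (0.91, adjusted p = 2.6e-07) and BRD3 (0.64, adjusted p = 0.0016) rose. HEXIM1, which codes for an inhibitor of the elongation factor P-TEFb and rises with BET inhibition in many cell types, was at least 1.23-fold higher (adjusted p = 0.014), its DMSO arrays being below background. NFKBIA (0.07), TCF3 (-0.19) and E2F1 (-0.12) did not pass, and CCND2 was below background. IL10 is uncertain: its reported probe did not pass (0.30, adjusted p = 0.13), being 11.89 to 12.43 in every group. A dimmer probe fell (-2.28, adjusted p = 6.3e-15 over probes). HEXIM1 lost its call without OTX015 replicate 3 or DMSO replicate 1, and BCL2 with the mean of its probes or without OTX015 replicate 2.

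The MYC list, raised on DMSO arrays, fell against them at 12 h in SUDHL2 in 25 of 27, 26 adjusted over the list alone. The list median was -1.02 (adjusted p = 6.4e-20, and adjusted p = 0.0014 with an estimated correlation). POLR3G (-2.10), NOP16 (-1.77) and WDR12 (-1.58) were among them. Histones rose in 22 of 23, also 22 adjusted over the list alone. The members had a median of 2.17 (adjusted p = 2.5e-22; adjusted p = 0.057 with an estimated correlation). Of 17 activated B-cell and plasma cell genes 11 fell and 1 rose, 11 and 1 adjusted over the list alone. The members' median was -0.79 (adjusted p = 1.1e-06; adjusted p = 0.057 with an estimated correlation), with ENTPD1 (-1.71), MZB1 (-1.49) and XBP1 (-0.97) down. Cell cycle inhibitors and p53 targets rose in 9 of 18, 10 adjusted over the list alone. The shift had a median of 0.46 (adjusted p = 5.7e-05; adjusted p = 0.057 with an estimated correlation), with CDKN2D (1.85), GADD45A (1.42) and CCNG2 (1.40, its probe detected on 2 of 3 DMSO arrays) up. Cholesterol synthesis genes rose in 8 of 13, 8 adjusted over the list alone. Their median was 0.35 (adjusted p = 0.0017; adjusted p = 0.16 with an estimated correlation), INSIG1 (1.14) and IDI1 (1.11) among them. Mitosis genes, lowered on DMSO arrays, rose against them in 6 of 20, 6 adjusted over the list alone. The list had a median of 0.28 (adjusted p = 0.048; adjusted p = 0.76 with an estimated correlation), BUB1 (0.80) being one. This shift was not called under 6 alternatives, scaling and background settings among them. The histone median was 1.41 without background correction.

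In SUDHL2 at 12 h the other lists held genes moving both ways. TNF rose (1.90 ± 0.16, adjusted p = 6.7e-13), the opposite of its fall at 1 h. In the NF-kB list 8 of 22 fell, BCL2A1 (-2.12) and CFLAR (-1.24) among them, and 1 rose (list adjusted p = 0.057, below 0.05 under 11 alternatives). In JAK-STAT and cytokine signalling 6 of 18 fell and 2 rose, with STAT3 (-1.66), SOCS1 (-1.42) and IL21R (-1.49) down (adjusted p = 0.082). The Toll-like receptor list had 7 fallen and 4 risen of 18, IRAK1 (-1.22) falling (adjusted p = 0.41). Interferon genes split 3 and 3 of 20, IRF7 (2.17) rising (adjusted p = 0.67). In the BCL2 family 5 of 16 fell and 2 rose, with BCL2L11 (-1.42) and BMF (-1.10) down (adjusted p = 0.35). B-cell receptor genes included 5 that fell and 4 that rose of 19, MS4A1 (-1.76) and CD79B (1.08) being examples (median 0.12, mean -0.04, adjusted p = 0.87). Germinal centre genes gave 4 fallen and 2 risen of 13, LMO2 (-1.42) falling (adjusted p = 0.37). The BET and P-TEFb list had 5 risen and 2 fallen of 16, MEPCE (1.05) up (adjusted p = 0.40).

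Immediate early genes in SUDHL2 at 12 h gave 5 risen and 4 fallen of 20, DUSP2 (-2.11) and IER5 (1.05) among them (median 0.28, adjusted p = 0.67). E2F and replication genes gave 7 fallen and 3 risen of 22, CCNE1 (-0.89) falling (median -0.16, adjusted p = 0.15). Amino acid stress genes gave 5 fallen and 2 risen of 15 (TRIB3 -1.65, DDIT4 1.72, list adjusted p = 0.29). Heat shock genes gave 2 fallen and 3 risen of 10 (HSPE1 -0.94, list adjusted p = 0.83), and antigen presentation genes 3 and 6 of 17 (HLA-DMB 0.92, list adjusted p = 0.77). Reference genes gave 2 risen and 1 fallen of 11 (SDHA 0.69, list adjusted p = 0.82; median -0.01, test upward). Markers of other cell types were few: both of the 2 T-cell and NK-cell genes fell (adjusted p = 0.18), as did 1 of 9 myeloid genes, C1QB (-0.87, list adjusted p = 0.87), and 1 of 3 stromal and epithelial genes, EPCAM (-1.56, list adjusted p = 0.12). For these 17 lists the counts adjusted over the list alone were the same with a few exceptions. There was 1 more gene fallen in the JAK-STAT, heat shock, antigen presentation and stromal lists, 1 more risen in the BET and antigen presentation lists, and 1 fewer fallen among the reference genes. Against untreated arrays SOCS1 was not lower, nor were BUB1, CCNG2 and DDIT4 higher.

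**Figure D1:**
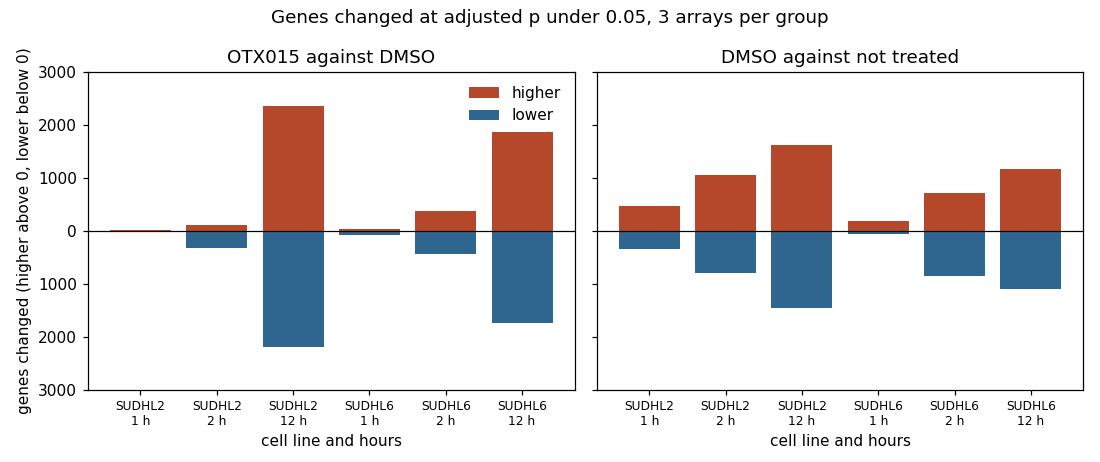
Number of genes changed at an adjusted p under 0.05 (vertical axis, higher above 0 and lower below 0) by cell line and hours, for OTX015 against DMSO and for DMSO against not treated, 3 arrays per group. OTX015 changed 25, 440 and 4569 genes in SUDHL2 and 110, 804 and 3597 in SUDHL6 at 1, 2 and 12 h.

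In SUDHL6 at 1 h, MYC had already fallen (-1.35 ± 0.22, adjusted p = 0.00031), with PIM1 (-1.12 ± 0.17, adjusted p = 0.00014) and CDKN1A (-0.88 ± 0.18, adjusted p = 0.0043). The largest falls were of the chemokine gene CCL3L3 (-2.12 ± 0.41, adjusted p = 0.0023, detected on 2 of 3 OTX015 arrays) and GPR18 (-1.84 ± 0.33, adjusted p = 0.00087). Then came the NF-kB feedback inhibitor TNFAIP3 (-1.74 ± 0.27, adjusted p = 0.00014), the G-protein regulator RGS1 (-1.66 ± 0.30, adjusted p = 0.001) and the p53 target SESN1 (-1.57 ± 0.14, adjusted p = 9.9e-10). H2BC21 (1.27 ± 0.25, adjusted p = 0.0027), IER3 (1.24 ± 0.20, adjusted p = 0.00036) and FAM43A (1.12 ± 0.21, adjusted p = 0.0023, detected on 2 of 3 DMSO arrays) rose most. TNFRSF12A and MIR425 were at least 1.74-fold (adjusted p = 0.00031) and 1.2-fold higher (adjusted p = 0.00014) than DMSO arrays without detection. In all 23 genes rose and 87 fell, 21 of the 110 at least 2-fold, while 11% did not overlap. Mean CDKN1A was 11.2 with OTX015 and 12.08 with DMSO, both above the 9.22 of untreated arrays, so it fell against DMSO only, as did SESN1, TNF and DUSP5. The rest of the fixed set lay between CCR7 (-0.45) and HEXIM1 (0.41, detected on 2 of 3 DMSO arrays) with adjusted p of 0.44 or more, and IL6 was below background.

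NF-kB targets were down as a list in SUDHL6 at 1 h (median -0.18, adjusted p = 4e-07; adjusted p = 0.08 with an estimated correlation). In it 5 of 22 had fallen and 1 had risen, 7 and 2 adjusted over the list alone, NFKBIE (-0.92, adjusted p = 0.00067) and TNF (-0.82, adjusted p = 0.0024) among the falls. Histones were up (median 0.41, adjusted p = 1.2e-10; adjusted p = 0.20 with an estimated correlation). H2BC21 was the 1 of 23 that rose over all genes, 3 adjusted over the list alone. Immediate early genes gave 2 risen and 1 fallen of 20, 8 and 2 adjusted over the list alone. The list median was 0.20 (adjusted p = 0.0045; adjusted p = 0.38 with an estimated correlation), DUSP5 (-0.98, adjusted p = 0.00014) being the fall. Replication genes (median -0.09, adjusted p = 0.00082; adjusted p = 0.49 with an estimated correlation) and mitosis genes (median -0.14, adjusted p = 0.018; adjusted p = 0.73 with an estimated correlation) shifted down. So did p53 targets (median -0.08, adjusted p = 0.034; adjusted p = 0.26 with an estimated correlation) and the Toll-like receptor list (adjusted p = 0.034; adjusted p = 0.43 with an estimated correlation). Heat shock genes shifted up (median 0.11, adjusted p = 0.046; adjusted p = 0.20 with an estimated correlation). The heat shock shift was not called under 8 alternatives. With only the groups compared, the shifts of p53 targets and of the Toll-like receptor list and the rises of H2BC21, FAM43A and TNFRSF12A were not called. H2BC21 also lost its call without OTX015 replicate 2 or DMSO replicate 3, FAM43A without DMSO replicate 3 and CDKN1A without DMSO replicate 2 or with the mean of its probes. The count of 110 was 66 and 64 without OTX015 replicates 1 and 2.

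At 2 h in SUDHL6, LSMEM1 (2.47 ± 0.18, adjusted p = 7.2e-13, detected on 2 of 3 DMSO arrays), the tubulin gene TUBB3 (2.19 ± 0.26, adjusted p = 1.1e-07), IER3 (2.18 ± 0.20, adjusted p = 4.8e-10) and the antiproliferative gene TOB1 (1.78 ± 0.24, adjusted p = 9.9e-07) rose most. The Notch modifier gene LFNG was at least 3.01-fold higher (adjusted p = 1.6e-11). MIR155HG (-2.21 ± 0.18, adjusted p = 1.3e-11), GPR18 (-2.06 ± 0.33, adjusted p = 2.1e-05) and the Toll-like receptor TLR1 (-1.90 ± 0.22, adjusted p = 5.4e-08) fell most. CLDN23 (-1.72 ± 0.17, adjusted p = 1.7e-09) and the interferon lambda receptor IFNLR1 (-1.56 ± 0.11, adjusted p = 7.2e-13) followed. PIM1 (-1.27, adjusted p = 1.4e-06), MYC (-1.22 ± 0.22, adjusted p = 0.00017) and BCL6 (-1, adjusted p = 0.00017) were lower. Mean PIM1 was 10.05 with OTX015, near the 10.11 of untreated arrays, and 11.32 with DMSO. HEXIM1 was higher (0.95 ± 0.16, adjusted p = 8.5e-05, detected on 2 of 3 DMSO arrays). In all 369 genes rose and 435 fell, 111 of the 804 at least 2-fold, and 18.8% did not overlap. Which direction held most changes depended on scaling: 45.9% were rises, and 59.6% with 75th percentile scaling. The remaining genes of the fixed set lay between CCR7 (-0.61, adjusted p = 0.56) and NFKBIA (0.38, adjusted p = 0.28). CCR7 was called with slide (-1.06) or experiment number (-0.61) as a block.

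Immediate early genes rose in SUDHL6 at 2 h in 9 of 20 cases with 1 fall, 14 and 1 adjusted over the list alone. The members had a median of 0.53 (adjusted p = 8.8e-09; adjusted p = 0.072 with an estimated correlation), JUN (1.77) and FOS (1.38) among them. Histones rose in 8 of 23, 14 adjusted over the list alone. The members' median was 0.66 (adjusted p = 6.9e-10; adjusted p = 0.21 with an estimated correlation), H2BC21 (1.46) and H2AC20 (1.03) included. NF-kB targets, raised on DMSO arrays, fell against them in 9 of 22 with 1 risen, 12 and 1 adjusted over the list alone. The shift had a median of -0.44 (adjusted p = 4.1e-07; adjusted p = 0.08 with an estimated correlation), led by NFKBIE (-1.51) and LTA (-1.15). In the Toll-like receptor list 6 of 18 fell, 6 adjusted over the list alone. Their median was -0.17 (adjusted p = 0.00011; adjusted p = 0.12 with an estimated correlation), TLR6 (-1.42) and TLR7 (-1.19) after TLR1. Replication genes (median -0.12, adjusted p = 0.0072; adjusted p = 0.63 with an estimated correlation) and mitosis genes (median -0.14, adjusted p = 0.0068; adjusted p = 0.68 with an estimated correlation) shifted down, but not with 75th percentile scaling or with slide as a block. Heat shock genes shifted up (median 0.05, adjusted p = 0.027; adjusted p = 0.16 with an estimated correlation), but not with only the groups compared. HSPA1B (1.69) and DNAJB1 (1.13) were the 2 of 10 that rose. In the MYC list 3 of 27 fell, 4 adjusted over the list alone, without a shift of the list (median -0.06, adjusted p = 0.11).

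At 12 h in SUDHL6 histone genes were again most of the largest rises: H2AC19 rose 6.5-fold (2.70 ± 0.24, adjusted p = 9.2e-12), followed by H2AC18 (2.70 ± 0.32), ZSWIM6 (2.53 ± 0.14, adjusted p = 4.9e-18) and H4C14 (2.40 ± 0.18). Next were H2AC20 (2.37 ± 0.20), H2BC21 (2.30 ± 0.25), H2BC5 (2.26 ± 0.33) and H2AJ (2.16 ± 0.21). Among the largest falls, FCRL4, an Fc receptor-like gene, was at least 7.45-fold lower (adjusted p = 4.9e-18) and SLC15A3 at least 4.64-fold lower (adjusted p = 2.1e-15). PVRIG (-3.19 ± 0.14, adjusted p = 1.3e-20), FCGBP (-3.17 ± 0.18) and the germinal centre serpin SERPINA9 (-3.15 ± 0.21, adjusted p = 3.1e-15) fell. So did the phosphatase gene PTPN6 (-2.76 ± 0.21, detected on 2 of 3 OTX015 arrays), the pre-B-cell receptor gene VPREB3 (-2.62 ± 0.21) and ACSL5 (-2.59 ± 0.14). In all 1861 genes rose and 1736 fell, 26.8% of those tested, 456 of them at least 2-fold. Among all genes 36.6% did not overlap.

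By 12 h MYC itself was no longer past the threshold in SUDHL6 (-0.50 ± 0.22, adjusted p = 0.09). It was with array weights, with the mean of its probes and without DMSO replicate 1. A dimmer MYC probe passed with a change of like size (-0.46 ± 0.15, adjusted p = 0.023 over probes). MYB (-0.88, adjusted p = 3e-05), MYD88 (-0.71, adjusted p = 8.1e-06) and the germinal centre factor TCF3 (-0.63, adjusted p = 0.00044) fell. BCL2 passed (adjusted p = 0.035) without a size, its probe being detected on 1 of 3 DMSO arrays and no OTX015 array, and its other 3 probes did not pass. CCND2 was at least 1.34-fold lower (adjusted p = 0.00056, detected on 2 of 3 DMSO arrays), but its other probe, about as bright, did not change (-0.05 ± 0.17, adjusted p = 0.88). PIM1 rose (0.80, adjusted p = 0.00042), the opposite of 1 h and 2 h, its mean being 10.31 with OTX015, 9.52 with DMSO and 10.11 untreated. Other rises were of SERPINI1 (1.01, adjusted p = 0.00032), CDKN1A (0.58, adjusted p = 0.013), BRD3 (0.51, adjusted p = 0.015) and HEXIM1 (0.48, adjusted p = 0.026, detected on 1 of 3 DMSO arrays). E2F1 (-0.42, adjusted p = 0.1), NFKBIA (-0.41, adjusted p = 0.1), BRD2 (0.26, adjusted p = 0.14), CCR7 (-0.68, adjusted p = 0.29), IL10 (0.12), BCL6 (-0.08) and IRF4 (-0.07) did not pass. CCR7 and NFKBIA did with slide or experiment number as a block. BCL2 lost its call under 8 alternatives, among them without OTX015 replicate 2 or 3 or DMSO replicate 3, HEXIM1 under 6, among them without replicate 1 or 3 of either group, and BRD3 without OTX015 replicate 2 or DMSO replicate 1. CDKN1A lost it with only the groups compared and without OTX015 replicate 1 or 2 or DMSO replicate 3, and CCND2 with 75th percentile scaling (-0.09).

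The MYC list, raised on DMSO arrays, fell against them in SUDHL6 at 12 h in 19 of 27, 21 adjusted over the list alone. The list had a median of -0.60 (adjusted p = 2.4e-11, and adjusted p = 0.027 with an estimated correlation), NOP16 (-1.44), POLR3G (-1.21) and MRTO4 (-1.10) among them. Histones rose in 18 of 23, 19 adjusted over the list alone. The list median was 1.48 (adjusted p = 1.8e-14; adjusted p = 0.12 with an estimated correlation), the median being 0.87 without background correction. Cell cycle inhibitors and p53 targets rose in 11 of 18, 11 adjusted over the list alone. The members had a median of 0.57 (adjusted p = 2.3e-05; adjusted p = 0.057 with an estimated correlation), TP53INP1 (1.75) and CDKN2D (1.37) being examples. Replication genes fell in 14 of 22, 17 adjusted over the list alone. The members' median was -0.48 (adjusted p = 4e-07; adjusted p = 0.25 with an estimated correlation), MCM5 (-1.13) and CDT1 (-1.12) included. The Toll-like receptor list fell in 11 of 18 with 1 risen, 11 and 1 adjusted over the list alone. The shift had a median of -0.76 (adjusted p = 4.7e-05; adjusted p = 0.11 with an estimated correlation), with TLR10 (-2.08) and IRAK1 (-1.35) down. B-cell receptor signalling fell in 11 of 19 with 1 risen, 11 and 1 adjusted over the list alone. Their median was -0.47 (adjusted p = 3e-04; adjusted p = 0.12 with an estimated correlation), with CD72 (-2.20), CD22 (-1.02) and CD79A (-0.63) down.

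Among NF-kB targets in SUDHL6 at 12 h 9 of 22 fell and 1 rose, 9 and 1 adjusted over the list alone. The list had a median of -0.35 (adjusted p = 0.00042; adjusted p = 0.21 with an estimated correlation), LTA (-2.12), CD83 (-1.75) and TNF (-1.30) falling. Activated B-cell and plasma cell genes fell in 8 of 17 with 1 risen, 8 and 1 adjusted over the list alone. The list median was -0.39 (adjusted p = 0.0027; adjusted p = 0.21 with an estimated correlation), MZB1 (-1.58) and XBP1 (-1.12) included. Antigen presentation genes fell in 6 of 17, 6 adjusted over the list alone. The members had a median of -0.22 (adjusted p = 0.015; adjusted p = 0.49 with an estimated correlation), with HLA-DOB (-1.71) and PSMB8 (-1.12) down, a shift not called with the mean of all probes. Other lists did not pass. JAK-STAT had 6 risen and 2 fallen of 18 (JAK1 1, list adjusted p = 0.39), interferon 3 and 5 of 20 (ISG15 -1.35, list adjusted p = 0.11) and BET and P-TEFb 7 and 1 of 16 (adjusted p = 0.10). The BCL2 family had 2 risen and 4 fallen of 16 (HRK 1.30, list adjusted p = 0.77), germinal centre genes 5 and 4 of 13 (LMO2 -2.07, median 0.12, mean -0.19, list adjusted p = 0.93) and immediate early genes 4 and 1 of 20 (JUND 1.33, list adjusted p = 0.18). In the same order, mitosis genes had 2 and 1 of 20 (adjusted p = 0.60), cholesterol synthesis 2 and 2 of 13 (median 0.04, mean -0.01, adjusted p = 0.97), and amino acid stress 3 and 7 of 15 (TRIB3 -1.22, list adjusted p = 0.067). Heat shock genes had 2 and 3 of 10 (HSPB1 -1.49, list adjusted p = 0.40) and reference genes 2 risen of 11 (adjusted p = 0.54). Their counts adjusted over the list alone were the same except for 1 more interferon gene and 2 more cholesterol genes fallen and 1 more BET and 1 more BCL2 family gene risen. Markers of T and NK cells (2 genes, median 0.01, adjusted p = 1), myeloid cells (9 genes, median -0.05, adjusted p = 0.83) and stromal and epithelial cells (3 genes, median -0.08, adjusted p = 0.83) did not shift.

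**Figure D2:**
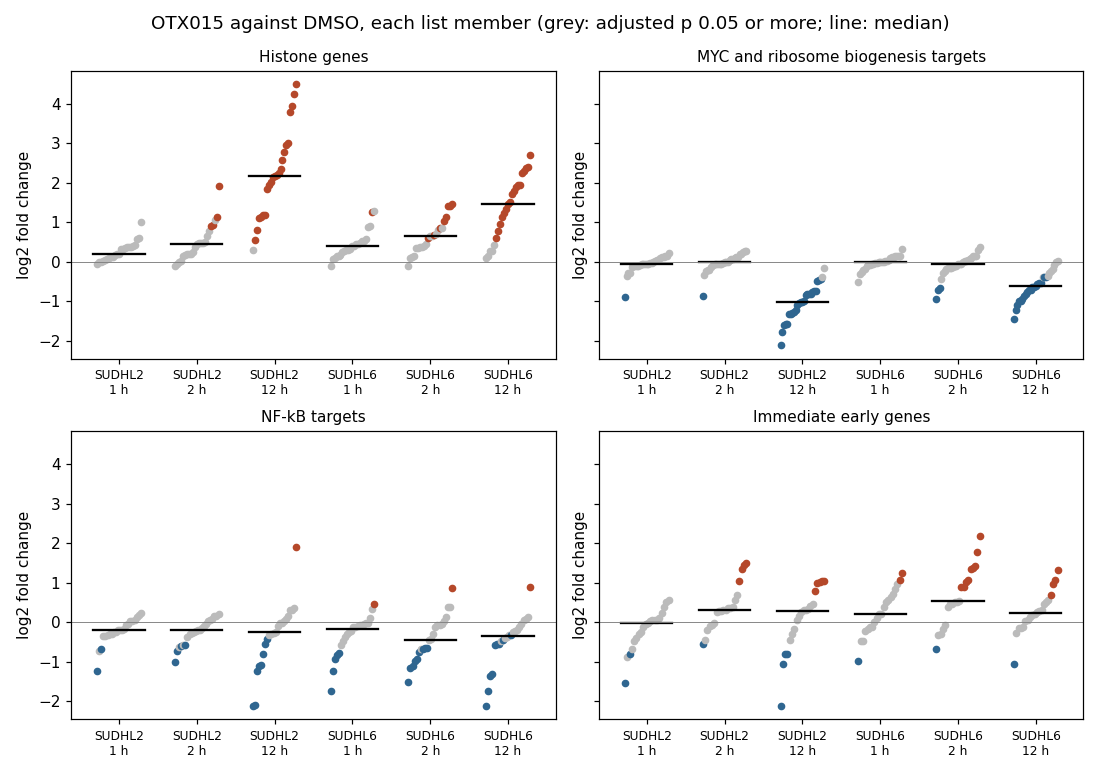
Log2 fold change for OTX015 against DMSO (vertical axis) of each measured member of 4 gene lists by line and hours, coloured where its adjusted p was under 0.05, with a line at the median. Histone medians reached 2.17 in SUDHL2 and 1.48 in SUDHL6 at 12 h, when MYC target medians were -1.02 and -0.60.

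How far the lines share the response was measured by overlap. At 12 h 1048 genes rose in both (328 expected by chance) and 956 fell in both (286 expected), while 111 changed in opposite directions (612 expected). Across genes, which are not independent replicates, the 2 responses had a Spearman rho of 0.521. At 2 h, 53 genes rose and 151 fell in both (3.06 and 10.7 expected) with rho 0.323, and at 1 h 1 rose and 10 fell in both (0.012 and 0.117 expected) with rho 0.055. Within a line, of the 440 genes of SUDHL2 at 2 h, 58 rose and 126 fell again at 12 h and 53 had turned (19.6, 54.1 and 76.3 expected). For the 804 of SUDHL6 the numbers were 219, 158 and 40 (51.2, 56.3 and 108 expected). Of the changes at 1 h, in SUDHL2 5 rose and 7 fell again at 12 h and 11 of 25 had turned (1.23, 2.96 and 4.33 expected, rho -0.081). In SUDHL6 the numbers were 14, 26 and 12 of 110 (3.19, 11.3 and 15.1 expected, rho 0.067). With slide as a block the counts for 1, 2 and 12 h were 36, 450 and 4831 in SUDHL2 and 146, 947 and 3860 in SUDHL6.

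Whether the lines differ in their response was tested directly as the SUDHL2 minus SUDHL6 response. At 1 h 5 genes differed, where 598 had an unadjusted p under 0.05. A difference has a size only where the gene was detected in all 4 groups compared, which held for 4 of these 5. SESN1 (1.72 ± 0.20, adjusted p = 1.4e-06) and AEN (1.42 ± 0.23, adjusted p = 0.0011) were relatively higher in SUDHL2. NR4A2 (-1.44 ± 0.25, adjusted p = 0.0046, detected on 1 of 3 SUDHL6 OTX015 arrays) and RGS2 (-0.87 ± 0.17, adjusted p = 0.028) were relatively lower. MIR425 passed (adjusted p = 0.035) but was detected only with OTX015 in SUDHL6, so its difference has no size. The difference for MYC at 1 h did not pass (0.80 ± 0.31, adjusted p = 1). At 2 h 37 genes were relatively higher and 53 lower, 69 of the 90 being detected in all 4 groups. ADARB1 (1.64 ± 0.26, detected on 2 of 3 SUDHL2 DMSO arrays) was relatively higher, and PTAFR was so by at least 2.51-fold. TOB1 (-2.10 ± 0.34, adjusted p = 0.00025) and TRIB1 (-1.93 ± 0.26) were relatively lower. CLDN23 and FAM43A, detected in SUDHL6 only, and TEX14 and ARHGEF10, detected in SUDHL2 only, passed without a size. Immediate early genes were relatively lower in SUDHL2 at 1 h (median -0.43, adjusted p = 3.2e-07; adjusted p = 0.14 with an estimated correlation) with 1 of 20 passing, 3 adjusted over the list alone. RGS2 lost its call under 10 alternatives, among them without replicate 1 or 2 of either SUDHL2 group or of SUDHL6 OTX015, or replicate 2 or 3 of SUDHL6 DMSO. MIR425 lost it under 11, among them without replicate 1 or 3 of any of the 4 groups or replicate 2 of SUDHL6 DMSO. NR4A2 lost it with only the groups compared. The count of 5 was 3 without OTX015 replicate 1 or DMSO replicate 1 of SUDHL2, or DMSO replicate 2 or 3 of SUDHL6.

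At 12 h the responses differed for 824 genes relatively higher and 821 relatively lower in SUDHL2, and 1251 of the 1645 were detected in all 4 groups. MYC was relatively lower in SUDHL2 (-2.97 ± 0.31, adjusted p = 2.7e-09), where it fell, while its change in SUDHL6 had not passed. So were IRF4 (-1.72, adjusted p = 2e-05) and BCL6 (-1.48, adjusted p = 5.5e-05), which fell against DMSO in SUDHL2 only. PIM1 (-1.76, adjusted p = 1.4e-06) was too, falling against DMSO in SUDHL2 and rising in SUDHL6. Mean IRF4 was 8.62 with OTX015, 9.15 untreated and 10.4 with DMSO in SUDHL2, and 7.51, 7.85 and 7.58 in SUDHL6. Mean PIM1 was 9.06, 9.08 and 10.02 in SUDHL2 and 10.31, 10.11 and 9.52 in SUDHL6. Much of the difference for IRF4 and PIM1 therefore lay in the DMSO arrays. Relatively higher in SUDHL2 were MIR3142HG (3.38 ± 0.21), TNF (3.20 ± 0.22, adjusted p = 3.1e-14) and C12orf57 (3.03 ± 0.18). Others were CCR7 (2.51 ± 0.63, adjusted p = 0.0054, detected on 2 of 3 arrays of each SUDHL6 group), BRD2 (0.65, adjusted p = 0.012) and CDKN1A (0.82, adjusted p = 0.025). Some genes passed without a size: CD36, IL12A and IL6 were detected in SUDHL2 only, FCRL4, SERPINA9 and CCND2 in SUDHL6 only, and TNIP3 in SUDHL6 on 1 DMSO array alone. The rest of the fixed set lay between MYB (-0.20) and SERPINI1 (0.65) with adjusted p of 0.14 or more. CDKN1A lost its call under 10 alternatives, among them without SUDHL2 OTX015 replicate 3, SUDHL2 DMSO replicate 2 or 3, SUDHL6 OTX015 replicate 3 or SUDHL6 DMSO replicate 1 or 2. The call was also lost for CCND2 with 75th percentile scaling, with the mean of its probes and without SUDHL6 DMSO replicate 2 or SUDHL2 DMSO replicate 3.

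As lists at 12 h, MYC targets were relatively lower in SUDHL2 (11 of 27, 13 adjusted over the list alone, median -0.48, adjusted p = 4.3e-06; adjusted p = 0.14 with an estimated correlation), WDR12 (-1.04) among them. Histone genes were relatively higher (7 of 23 with 1 lower, 11 and 1 adjusted over the list alone, median 0.71, adjusted p = 3.2e-07; adjusted p = 0.35 with an estimated correlation), H3C10 (1.98, detected on 1 of 3 SUDHL2 DMSO arrays) and H1-2 (1.66) among them. B-cell receptor genes, which fell as a list in SUDHL6, were relatively higher in SUDHL2 (9 of 19 with 2 lower, 11 and 2 adjusted over the list alone, median 0.56, adjusted p = 0.00033; adjusted p = 0.14 with an estimated correlation), CD22 (1.34) and CD79B (1.27) among them. So were cholesterol synthesis (6 of 13, 6 adjusted over the list alone, median 0.54, adjusted p = 0.00034; adjusted p = 0.14 with an estimated correlation), with IDI1 (0.94). Antigen presentation genes were too (5 of 17, 6 adjusted over the list alone, median 0.24, adjusted p = 0.0029; adjusted p = 0.36 with an estimated correlation), with HLA-DMB (1.41). The Toll-like receptor list (6 of 18, 6 adjusted over the list alone, median 0.30, adjusted p = 0.0029; adjusted p = 0.30 with an estimated correlation) was relatively higher. Interferon genes were as well (6 of 20, 6 adjusted over the list alone, median 0.08, adjusted p = 0.014; adjusted p = 0.37 with an estimated correlation), ISG15 (2.05) included. JAK-STAT genes were relatively lower (5 of 18 with 1 higher, 5 and 3 adjusted over the list alone, median -0.29, adjusted p = 0.0098; adjusted p = 0.30 with an estimated correlation), STAT3 (-2.53) and SOCS1 (-2.38) among them.

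Comparing 12 h with 1 h within a line showed how the difference between OTX015 and DMSO arrays changed. This difference also moves when the DMSO arrays change. In SUDHL2 1515 genes were higher and 1527 lower in the later response, 880 by at least 2-fold. MIR3142HG (4.19 ± 0.21) and CD69 (4.17 ± 0.62) had fallen at 1 h, and H2AC19 (3.88 ± 0.34) and H2AC20 (3.86 ± 0.28) followed. CD36 (-3.57 ± 0.22), IL12A (-3.50 ± 0.24), TNIP3 (-3.28 ± 0.22), SMPDL3A (-3.03 ± 0.21) and MYC (-2.92 ± 0.31, adjusted p = 2.3e-09) were lower later. In SUDHL6 1039 genes were higher and 995 lower later, 472 by at least 2-fold. These included ZSWIM6 (2.61 ± 0.20), TP53INP1 (2.57 ± 0.40), SESN1 (2.49 ± 0.20) and CXCR4 (2.44 ± 0.34) among the higher. FCRL4, not detected with OTX015 at 12 h, was at least 7.08-fold lower later, and PVRIG (-3.39 ± 0.20), FCGBP (-3.20 ± 0.26) and SERPINA9 (-2.93 ± 0.30) were lower too. PIM1 (1.92, adjusted p = 2.3e-07), CDKN1A (1.46, adjusted p = 4.6e-05) and SERPINI1 (1.14, adjusted p = 0.0075) were higher in the later SUDHL6 response. Mean CDKN1A fell there from 11.2 to 9.42 with OTX015, and further, from 12.08 to 8.84, with DMSO. The later MYC response did not differ from the earlier one by the threshold (0.85 ± 0.31, adjusted p = 0.061). The later minus earlier IL10 response of SUDHL2 (0.59, adjusted p = 0.043) is uncertain, its probes going opposite ways.

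**Figure D3:**
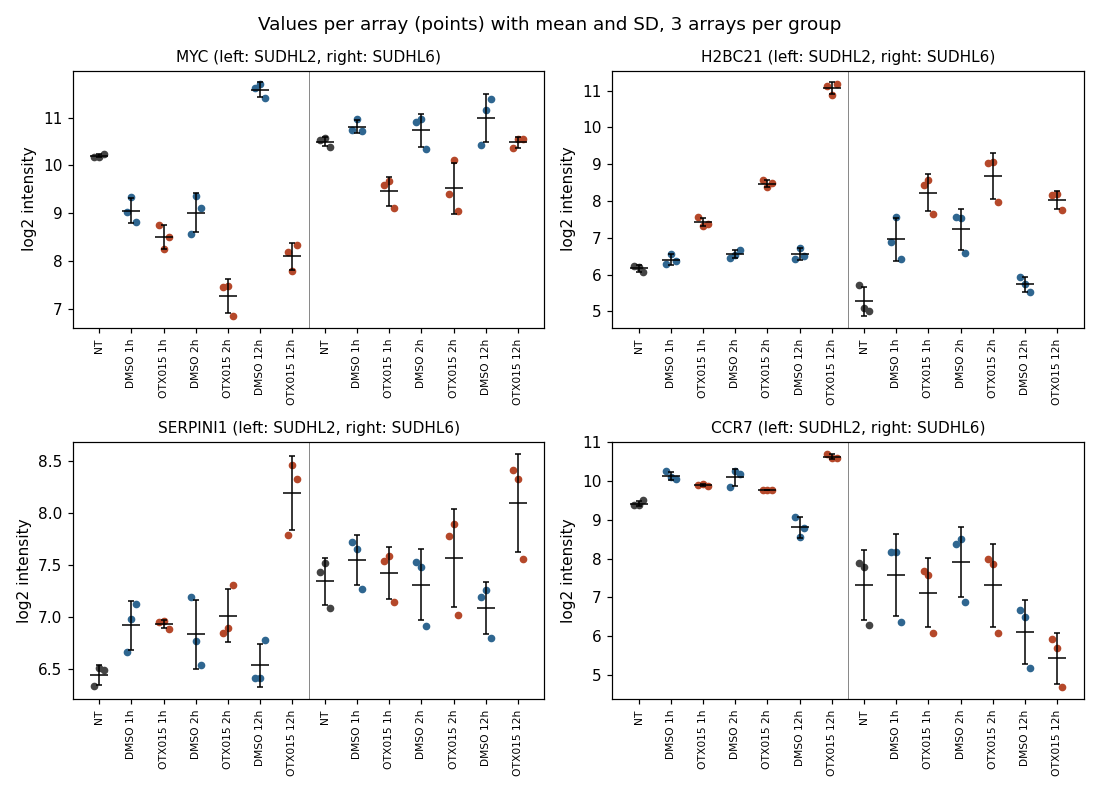
Log2 intensity (vertical axis) of MYC, H2BC21, SERPINI1 and CCR7 on each array (points) with mean and SD, by group, SUDHL2 at left and SUDHL6 at right of each panel. Mean MYC after 12 h was 8.1 with OTX015 and 11.58 with DMSO in SUDHL2, and 10.48 and 10.99 in SUDHL6.

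DMSO arrays were set against untreated arrays to show what changes without the drug, be it from vehicle or from handling. In SUDHL2 at 1 h, CD69 (2.77 ± 0.44, adjusted p = 5.3e-05) rose and the heat shock gene HSPA6 was at least 4.28-fold higher (adjusted p = 4.5e-16). STMN3 (-1.83 ± 0.15, adjusted p = 7.2e-12) and MIR155HG (-1.50 ± 0.18, adjusted p = 2.8e-07) fell, and MYC fell too (-1.14, adjusted p = 0.00079). At 2 h GPR18 (2.42 ± 0.33, adjusted p = 6.9e-07) rose and HSPA6 was at least 3.79-fold higher. DDIT4 (-2.63 ± 0.18, adjusted p = 1.3e-13) and HILPDA (-2.33 ± 0.20, adjusted p = 1.5e-11) fell at 2 h, as did MYC (-1.19, adjusted p = 0.00015) and IRF4 (-0.93, adjusted p = 0.00078). At 12 h the opposite held for MYC (1.38, adjusted p = 6.5e-06) and IRF4 (1.26, adjusted p = 4.5e-06). At that hour PNOC (2.36 ± 0.13, adjusted p = 1.1e-16) and MT1G (2.20 ± 0.29) rose most, and EFCAB3 (-2.59 ± 0.24) and ENO2 (-2.52 ± 0.19) fell most. Mean MYC intensity in SUDHL2 was 10.2 ± 0.029 (SD) untreated and 9.06 ± 0.27, 9.01 ± 0.41 and 11.58 ± 0.15 with DMSO at 1, 2 and 12 h. With OTX015 it was 8.5 ± 0.26, 7.27 ± 0.36 and 8.1 ± 0.28 (n = 3 each). Genes risen and fallen numbered 469 and 351, 1060 and 800, and 1620 and 1452 at the 3 hours, with 29.4, 31.8 and 40.3% of genes not overlapping. At 1 h 57.2% of the changes were rises, and 42.4% with 75th percentile scaling. The 1 h count of 820 was 471 without DMSO replicate 1 and 539, 456 and 447 without untreated replicates 1, 2 and 3, and the 2 h count of 1860 was 1238 without untreated replicate 3.

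In SUDHL6 arrays with DMSO at 1 h, CD69 (3.48 ± 0.44, adjusted p = 5e-07), JUN (3.08 ± 0.31, adjusted p = 2.8e-09, detected on 2 of 3 untreated arrays), CDKN1A (2.86 ± 0.18, adjusted p = 1.5e-15) and NFKBIA (1.89, adjusted p = 7.6e-10) rose. DDIT4 (-1.55 ± 0.18) fell and SPRY1 was at least 2.27-fold lower (adjusted p = 7.5e-06). At 2 h CD69 (2.97 ± 0.44, adjusted p = 3.6e-06), RGS16 (2.81 ± 0.20, adjusted p = 4.2e-14, detected on 2 of 3 untreated arrays), CDKN1A (2.57), IRF4 (1.51, adjusted p = 3.7e-07) and PIM1 (1.21, adjusted p = 2.4e-06) rose. ANKRD37 (-1.99 ± 0.22) and HILPDA (-1.94 ± 0.20) fell at 2 h. At 12 h MT1X (1.35 ± 0.28, adjusted p = 0.00043) and RPP40 (1.34 ± 0.16) rose and PFKFB4 (-3.41 ± 0.22, adjusted p = 4.6e-15) and LRRC32 (-3.20 ± 0.24) fell. MYC did not pass at 12 h (0.50, adjusted p = 0.13). Genes risen and fallen numbered 178 and 61, 711 and 858, and 1163 and 1092, with 14.4, 25 and 29.3% not overlapping. The 1 h count of 239 was 153 and 152 without untreated replicates 1 and 2.

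As lists, MYC targets were lower on DMSO than on untreated arrays in SUDHL2 at 1 h (12 of 27 fell, 19 adjusted over the list alone, median -0.36, adjusted p = 4.6e-13) and 2 h (14, 16 adjusted over the list alone, median -0.38, adjusted p = 1e-09). They were higher at 12 h in SUDHL2 (16, 19 adjusted over the list alone, median 0.52, adjusted p = 6.1e-08) and SUDHL6 (17 with 1 fallen, 20 and 1 adjusted over the list alone, median 0.50, adjusted p = 6.8e-13). These shifts held with an estimated correlation. Immediate early genes rose in SUDHL2 at 1 h (10 of 20 with 1 fallen, 11 and 1 adjusted over the list alone, median 0.74, adjusted p = 6.5e-11). They rose in SUDHL6 at 1 h (13, 16 adjusted over the list alone, median 1.13, adjusted p = 6.4e-41) and 2 h (11, 14 adjusted over the list alone, median 0.86, adjusted p = 2.8e-17), and these shifts held with an estimated correlation. In SUDHL6 at 2 h NF-kB targets (12 of 22, 13 adjusted over the list alone, median 0.79, adjusted p = 1e-15, and adjusted p = 0.0021 with an estimated correlation) were up. So were p53 targets (10 of 18 with 1 fallen, 10 and 1 adjusted over the list alone, median 0.60, adjusted p = 1.8e-09, and adjusted p = 0.0018 with an estimated correlation). Replication genes fell at 12 h in SUDHL2 (17 of 22, with 18 fallen and 1 risen adjusted over the list alone, median -0.65, adjusted p = 3.1e-12; adjusted p = 0.073 with an estimated correlation). They also fell in SUDHL6 (11 of 22, 14 adjusted over the list alone, median -0.40, adjusted p = 4.4e-08; adjusted p = 0.21 with an estimated correlation). Mitosis genes fell at 12 h in SUDHL2 (13 of 20, 16 adjusted over the list alone, median -0.69, adjusted p = 2e-09; adjusted p = 0.23 with an estimated correlation). In SUDHL6 they fell too (9 of 20, 11 adjusted over the list alone, median -0.41, adjusted p = 2.5e-05; adjusted p = 0.45 with an estimated correlation). Between the lines the DMSO responses had a Spearman rho across genes of 0.067, 0.206 and 0.455 at 1, 2 and 12 h.

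The untreated lines were compared to show the state in which each meets the drug. SUDHL2 expressed the muscle actin gene ACTG2 at least 123-fold higher (adjusted p = 5e-34), FEZ1 at least 77.2-fold, GTSF1 at least 72.5-fold, SPIC at least 47.4-fold and TRPM4 at least 28.7-fold. Also higher were the adhesion receptor CD44 (6.69 ± 0.18, detected on 1 of 3 SUDHL6 arrays), TPM2 (6.38 ± 0.12, detected on 2 of 3) and ANXA2 (5.99 ± 0.19). SUDHL6 expressed TUBB2B (-6.76 ± 0.11), EVL (-6.46 ± 0.13), PHGDH (-6.31 ± 0.13, detected on 1 of 3 SUDHL2 arrays), BNIP3 (-5.81 ± 0.14, detected on 1 of 3) and RGCC (-5.79 ± 0.16, detected on 2 of 3) more highly. HLA-DRB1, APOD and DEPTOR were at least 53.2, 45.2 and 39.4-fold lower in SUDHL2. IL6 was at least 4.97-fold higher in SUDHL2 (adjusted p = 8.4e-21), as were NFKBIA (2.29, adjusted p = 3e-14), CCR7 (2.10, adjusted p = 0.00011) and IRF4 (1.30, adjusted p = 3.3e-07). TCF3 (-2.51, adjusted p = 2e-19), PIM1 (-1.03), CDKN1A (-0.98), SERPINI1 (-0.90), BCL6 (-0.88, adjusted p = 6e-05), BRD2 (-0.65), MYB (-0.65) and E2F1 (-0.46, adjusted p = 0.041) were lower, the call of E2F1 being lost under 7 alternatives, among them without SUDHL2 replicate 2 or 3 or SUDHL6 replicate 3. CCND2 was at least 2.11-fold lower (adjusted p = 1.3e-09). MYC (-0.29, adjusted p = 0.29), BRD3 (0.36, adjusted p = 0.058), MYD88 (-0.07) and HEXIM1 did not differ by the threshold. BCL2 (3.12) and IL10 (-0.31) are uncertain.

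In all 3616 genes were higher and 3401 lower in untreated SUDHL2, 2465 of them at least 2-fold, while 61.7% did not overlap. Germinal centre genes were lower in 11 of 13 cases with 1 higher, 11 and 1 adjusted over the list alone. The members' median was -2.52 (adjusted p = 7e-07, and adjusted p = 6.1e-05 with an estimated correlation), GCSAM and MME being at least 11.8 and 9.88-fold lower. Heat shock genes were higher in 8 of 10 with 1 lower, 8 and 1 adjusted over the list alone. The shift had a median of 1.02 (adjusted p = 0.00025, and adjusted p = 0.011 with an estimated correlation). Activated B-cell and plasma cell genes were higher in 12 of 17 with 2 lower, 12 and 3 adjusted over the list alone. Their median was 1.23 (adjusted p = 8.7e-05; adjusted p = 0.082 with an estimated correlation), PRDM1 at least 29.5-fold. NF-kB targets were higher in 14 of 22 with 4 lower, 14 and 4 adjusted over the list alone. The list had a median of 0.94 (adjusted p = 0.00094; adjusted p = 0.24 with an estimated correlation). Antigen presentation genes were lower in 11 of 17 with 4 higher, 11 and 4 adjusted over the list alone. The list median was -2.36 (adjusted p = 6.9e-05; adjusted p = 0.22 with an estimated correlation). B-cell receptor genes were lower in 12 of 19 with 4 higher, 12 and 4 adjusted over the list alone. The members had a median of -0.71 (adjusted p = 0.02; adjusted p = 0.25 with an estimated correlation).

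Across the panel of 22 untreated lines, MYC had a median log2 intensity of 11.29 and ranged from 8.53 in U-2932 to 12.12 in OCI-Ly19. IRF4 ranged from 5.31 in SU-DHL-7 to 10.86 in TMD8 around a median of 8.38. BCL6, below background in DoHH2, reached 12.22 in OCI-Ly1 (median 10.61), and BCL2 reached 12.38 in RIVA (median 8.26). PIM1, below background in WSUDLCL2, reached 12.67 in HBL-1. CCR7 was detected in 19 lines and highest in OCI-Ly10 (12.68), SERPINI1 in 18 and highest in SU-DHL-4 (9.96), CCND2 in 10 and highest in HBL-1 (12.59), and IL6 in 6 and highest in SU-DHL-2 (9.91). The BET gene BRD2 varied less, from 9.64 in RCK8 to 11.37 in RIVA, and HEXIM1, detected in 16 lines, was at most 5.74. The panel arrays of SU-DHL-2 and SU-DHL-6 were each closest of the 22 to the untreated arrays of the same line (Spearman rho across genes 0.956 and 0.966, next lines 0.891 and 0.914).

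Lines with more IRF4 also had higher NF-kB targets: IRF4 and the mean of the NF-kB list correlated with r = 0.65 (permutation p = 0.0014, adjusted p = 0.0056) and rho = 0.59 (permutation p = 0.004, adjusted p = 0.008). Without Karpas-422 r was 0.69, as without SU-DHL-7 and WSUDLCL2, the lines farthest from the IRF4 median. Within slides with enough lines it was 0.73 on slide 4 (10 lines, permutation p = 0.016) and 0.80 on slide 5 (8 lines, exact permutation p = 0.0059). The NF-kB mean was lowest in SU-DHL-10 (6.92) and highest in OCI-Ly10 (9.67). MYC and the mean of the MYC list gave r = 0.36 (permutation p = 0.10, adjusted p = 0.10) and rho = 0.38 (permutation p = 0.078, adjusted p = 0.10), which did not pass. That r was 0.27 with the authors' values, 0.31 without Karpas-422, 0.41 without U-2932 and OCI-Ly19, 0.39 on slide 4 and 0.70 on slide 5, with rho of 0.22, 0.30, 0.26, 0.43 and 0.55.

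**Figure D4:**
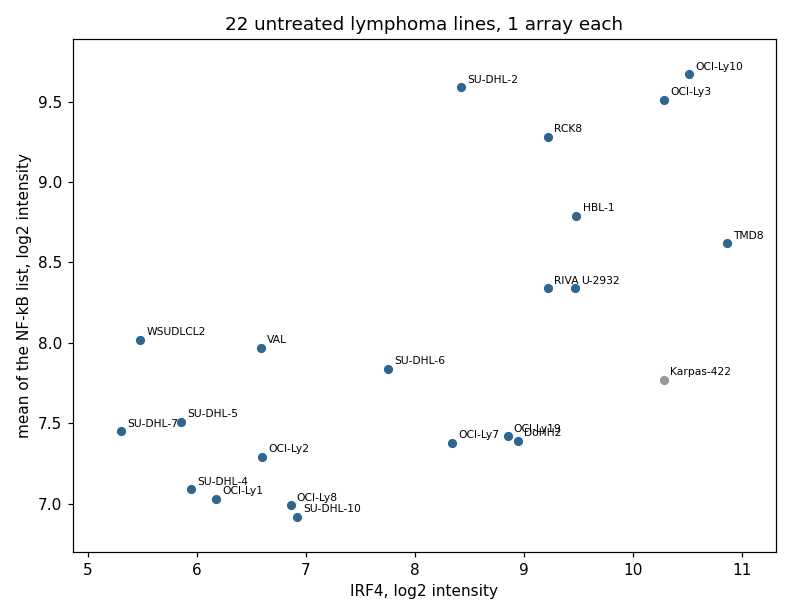
Mean log2 intensity of the NF-kB target list (vertical axis) against IRF4 log2 intensity (horizontal axis) in 22 untreated lymphoma lines, 1 array each, with Karpas-422 in grey. The 2 measures correlated at r = 0.65.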

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

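The tests in this part were fixed before their results were seen, apart from 1 count named below. Differences between the lines in the OTX015 response stood out because the difference itself was tested. It passed for 5 genes at 1 h, 90 at 2 h and 1645 at 12 h, MYC (-2.97 at 12 h) being relatively lower and TNF (3.20) relatively higher in SUDHL2. Of these, 4, 69 and 1251 genes were detected in all 4 groups compared, and the others have no full size. This count of detection was added after the results were seen. Of 100 splits of the arrays, 9, 11 and 8 gave as many genes, the real one included, so this count of splits does not exclude chance. The highest other splits gave 27, 567 and 3400 genes. These high numbers point to a structure of the samples: each of the 8, 10 and 7 other splits as large kept 1 of the 2 drug responses in its real grouping. The 81 splits that mixed both gave at most 1, 4 and 1 genes.

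The response at 12 h differed from that at 1 h for 3042 genes in SUDHL2 and 2034 in SUDHL6, again by a test of the difference itself. Of 100 splits 3 and 4 gave as many genes, the real one included, a share that decides nothing here. The highest other splits gave 3389 and 2503 genes. They kept 1 of the 2 responses, with its drug effect, in its real grouping. The 81 that mixed both diluted it and gave at most 2 and 21. Splits also ignored the pairing seen in SUDHL6.

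A pattern behind the 12 h difference was weighed: genes that were higher in 1 untreated line tended to fall more in that line. Across 13403 genes the untreated difference and the difference in response had a Spearman rho of -0.189 (95% interval -0.208 to -0.134 over 1000 resamples of the arrays), with no array shared between the 2 measures. Among 6071 genes in the middle of the range in every group, rho was -0.205 (-0.233 to -0.137). That filter uses the response groups, so it cannot exclude a floor or ceiling of the array. A candidate explanation, as a hypothesis, is that BET inhibition lowers preferentially what a line expresses highly. Genes are not independent replicates.

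Probes without a gene symbol were left out of the comparisons of genes, and they changed too. At 12 h 1162 of 7831 such probes changed in SUDHL2 (585 higher and 577 lower, 14.8%) and 782 in SUDHL6 (392 and 390, 9.99%). Among probes with a symbol the shares were 30.3 and 23.3%. At 1 h 8 and 29 unnamed probes changed. What these probes detect was not examined.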

How the results depend on the processing

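Of the alternatives here, the filter at 1.5 times the background mode, the normexp offset of 50, the panel without Karpas-422 and the omission of the third SUDHL6 experiment were chosen after the data were seen. Among counts of genes changed, 346 stayed within 1.5 times the reported value and 43 did not. Among values of named genes, 26174 kept their side of the threshold, 458 lost a call, 350 gained one and 1 turned. That one was the 12 h minus 1 h response of IL10 in SUDHL2, 0.59 as reported and -0.91 with the mean of all probes, whose probes go opposite ways. Calls of gene lists kept their side in 3111 tests, were lost in 109 and gained in 83. With an estimated correlation 54 of 207 list tests were lost, among them all but the MYC list for OTX015 against DMSO, and with fry 20 were lost and 19 gained. Both panel relations kept their side of the threshold in all 12 alternatives.

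Counts for OTX015 against DMSO at 12 h stayed within 1.5 times in both lines under every alternative run. In SUDHL2 the 1 h count of 25 was 47 with the experiment number as a block and 58 with array weights, and the 2 h count of 440 was 786 with array weights. With only the groups compared, 440 was 256, and in SUDHL6 110 was 28 and 804 was 372, this setting having fewer arrays to estimate the spread from. With untreated arrays in place of DMSO, 25 was 646, 440 was 1625, 110 was 278 and 804 was 1429, since this control adds whatever sets DMSO apart from untreated arrays. For DMSO against not treated, array weights gave 2088 in place of 820 and 3585 in place of 1860 in SUDHL2 at 1 h and 2 h, and only the groups compared gave 1434 in place of 820, and 137 in place of 239 in SUDHL6 at 1 h.

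The difference between lines at 1 h, 5 genes, was 15 without background correction, 13 with the authors' values, 11 with every probe, 17 with the experiment number as a block, 9 with offset 50, 3 with only the groups compared and 14 without the third SUDHL6 experiment. At 2 h, 90 was 144 with the authors' values, 149 with the experiment number as a block, 167 with array weights and 30 with only the groups compared. In the untreated lines 7017 was 11620 with every probe, where 26047 probes were tested in place of 13403 genes. For the other settings above the cause was not tested.

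Leaving out each array in turn, which leaves fewer arrays, gave 15 to 22 genes for SUDHL2 at 1 h (15 without OTX015 replicate 1, 16 without DMSO replicate 1 or 2), 289 to 347 at 2 h (289 without OTX015 replicate 1) and 64 to 90 for SUDHL6 at 1 h (66 and 64 without OTX015 replicates 1 and 2). For DMSO against not treated it gave 447 to 659 in SUDHL2 at 1 h and 1238 to 1765 at 2 h (low counts named above). In SUDHL6 at 1 h it gave 152 to 219 (153 and 152 without untreated replicates 1 and 2). The difference between lines at 1 h ranged from 3 to 6, being 3 without arrays named above. At 12 h the ranges were 3872 to 4219 in SUDHL2, 2979 to 3291 in SUDHL6 and 1276 to 1603 for their difference.

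The share of changes that were rises moved by over 10 points in 21 of 389 cases, 17 of them crossing 50%. With 75th percentile scaling it was 59.6% in place of 45.9% for OTX015 in SUDHL6 at 2 h, 42.4% in place of 57.2% for DMSO in SUDHL2 at 1 h (46.6% with every probe) and 30.5% in place of 41.1% for the difference between lines at 2 h. For OTX015 in SUDHL2 at 1 h, 28% was 16.1% without background correction, 16.7% with offset 50 and 12.9% with the authors' values. With untreated arrays in place of DMSO the share was 56.8, 54.6 and 52.2% in place of 28, 25.2 and 20.9% in SUDHL2 at 1 h and 2 h and SUDHL6 at 1 h. For the 5 genes of the difference between lines at 1 h, 40% moved so in 11 of 26 alternatives, up to 100% with only the groups compared, so that share has no stable direction. The median of all genes moved most between the untreated lines, being -0.0956 with 75th percentile scaling in place of 0.00709.

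Equal replicate numbers did not pair the arrays in SUDHL2, where residuals of 15 of 63 same-number pairs correlated above 0.1 and 8 of 21 arrays matched their own number best. In SUDHL6 it was 50 of 63 and 18 of 21. Signal over background limited what could be sized. Genes undetected in a group have only lower bounds, and without background correction the 12 h histone medians were 1.41 and 0.87 in place of 2.17 and 1.48. Stricter filters left some members out, so lists had 198 values in place of 207 with the filter at 1.5 times the mode, and named genes 1220 with that filter and 1270 with detection on all 3 arrays of a group in place of 1307.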

Other observations

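The slide test of the DMSO arrays and the S phase test of the histone genes were chosen after the results were seen. Between DMSO and untreated arrays further gene lists differed beyond those described above. In SUDHL2 amino acid stress genes rose in 8 of 15 cases with 1 fallen at 1 h, 10 and 1 adjusted over the list alone (median 0.55, adjusted p = 9.3e-11), and 8 rose with 1 fallen at 2 h, 9 and 2 adjusted over the list alone (median 0.48, adjusted p = 3.4e-05). Heat shock genes fell there in 3 of 10 at 1 h, 6 adjusted over the list alone (median -0.32, adjusted p = 0.00012), and 5 fell with 1 risen at 2 h, the same adjusted over the list alone (median -0.38, adjusted p = 0.002). In SUDHL6 at 2 h the BCL2 family rose in 8 of 16 with 1 fallen, 9 and 1 adjusted over the list alone (median 0.42, adjusted p = 0.00035), and cholesterol synthesis in 6 of 13, 8 adjusted over the list alone (median 0.35, adjusted p = 3.5e-06). At 12 h heat shock genes rose in 5 of 10, 5 adjusted over the list alone (median 0.43, adjusted p = 0.00026), and germinal centre genes fell in 5 of 13 with 1 risen, 6 and 2 adjusted over the list alone (median -0.36, adjusted p = 0.0082). These calls held with an estimated correlation, at adjusted p of 0.022 or less.

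In untreated SUDHL2 CD38 was at least 21.2-fold lower than in SUDHL6 and LY86 at least 32.4-fold lower, and the repressor BACH2 at least 8.12-fold lower.

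The array labelled Karpas-422 differed between deposited tables. Its signals, used for the panel, were unlike a B-cell line. CD3D was 11.14 against 6.61 to 7.33 in the other 21 lines, CD79A 6.98 against 9.75 to 13.11 and CD79B 7.94 against 10.5 to 13.58. In its processed column CD3D was 7.65, CD79A 12.65 and CD79B 12.33. Its columns correlated at 0.8815, and those of every other array at 0.9941 or more. Its germinal centre mean from signals was the panel's lowest (5.83).

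DMSO arrays differed from untreated arrays by 239 to 3072 genes, and technical causes were weighed. With slide as a block each count came to at least 100% of that reported, which argues against slide as the whole cause. The genes were partly others, 686 of 820 being shared in SUDHL2 at 1 h, the lowest share. With each array's detected share as a covariate the count was at least 66%, SUDHL2 at 1 h going from 820 to 541, so array quality does not account for the whole. Handling or a response to vehicle shared by both lines stays open, and how untreated cultures were handled is not given in the sources used here. The lines' responses had a rho of 0.067 at 1 h and 0.455 at 12 h.

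Histone genes rose at 12 h in both lines. Whether more cells were in S phase stays open. The E2F and DNA replication list had medians of -0.16 in SUDHL2 and -0.48 in SUDHL6, but OTX015 may lower these genes itself. Across background and scaling settings at least 58.8% of the median rise was left, which argues against normalization as the whole cause. The rise may be a response to BET inhibition, as a hypothesis from the same data.

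For each comparison of 3 against 3 arrays only 10 splits exist, so no share under 0.1 can be had, and the real split was the 1 of 10 with as many genes. Real and highest other counts for OTX015 were 25 and 0, 440 and 1, and 4569 and 1 in SUDHL2 at 1, 2 and 12 h, and 110 and 0, 804 and 30, and 3597 and 75 in SUDHL6. The 30 and 75 came from splits that part 1 of the 3 pairs, and the 3 other splits that part all pairs gave 0. For DMSO they were 820 and 0, 1860 and 0, and 3072 and 0 in SUDHL2, and 239 and 0, 1569 and 7, and 2255 and 3 in SUDHL6. Untreated lines gave 7017 and 0.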
